A study of Rattus norvegicus with 12 samples.

How the data were processed

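RNA was measured in 12 samples of rat lumbar spinal cord tissue, 3 each from sham animals at day 0 and from days 3, 7 and 14 after SCI. Per the labels, total RNA was extracted on columns and libraries were made with a SMARTer mRNA-Seq kit. The table held 2 kinds of value for each sample. The deposited counts are raw read counts per gene, which the authors did not normalise, per the file headers. The deposited FPKM values are counts that the authors scaled per kilobase of gene model and per library total, per the file headers. The FPKM values were proportional to the counts within a gene, with a largest deviation of 0.45% over 9502 genes with more than 500 counts in every library, and were not used here. The aligner, the counting tool, the treatment of reads that match several genes and the use of strand are not given in the sources used here. Values of overlapping genes, antisense transcripts and near-identical copies are therefore uncertain. The submitters' processing notes list the builds GRCm38 and mm10, which are mouse builds, while the gene identifiers are rat Ensembl identifiers. Chromosome names are those of the table, and no coordinates are given.

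The table listed 23526 genes, each with at least 1 count, of which 4095 had an identifier in place of a symbol. No pair of libraries was a copy of another, since the closest pair differed with a chi-square per gene of 67.6. Genes were filtered with edgeR's filterByExpr by group, which left 18714 and removed 4812, and libraries were scaled with TMM factors. Negative binomial models with 1 mean per group were fitted to all 12 libraries together, with 8 residual degrees of freedom, in edgeR 4.0.16 under R 4.3.3. Each comparison used edgeR's quasi-likelihood test, and p-values were adjusted by the Benjamini-Hochberg method with a limit of 0.05. The comparisons were each SCI day with sham, each pair of SCI days, and the 4 groups together. CPM values are given as mean ± SD of 3 libraries, and log2 fold changes with an SE. That SE is the size of the log2 fold change divided by the square root of the test's F statistic. It therefore restates the test and is not a separate estimate. Where a gene had no counts in sham, its fold is a lower bound against a floor of 3 counts over the sham group, and such floors cover counting error only.

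The 44 gene lists covered glial, immune, neuronal, vascular and metabolic groups and markers of other tissues that a lumbar sample can hold. Of their 867 symbols, 82 had no match in the table, and a symbol with several entries (167 symbols in the table) was taken at the entry with the most counts. Lists with at least 5 tested members were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it, and adjusted p-values were taken over the lists of a comparison. For each list, the members that passed were counted over all genes tested and adjusted over the list alone.

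The groups, tests, lists, alternatives and the rule for named genes were chosen before the data were examined. List tests were planned for each day against sham, and those between days were not part of the plan. For each comparison with sham the rule took up to 6 genes with the largest rise and 6 with the largest fall among those that passed, had at least 5 CPM in the higher group and did not overlap between groups. Between days it took 3 each way. It also took up to 4 members with the smallest p of each list described, and 9 genes in every comparison with sham: Gfap, Aif1, Cd68, Mbp, Chat, Slc12a5, Htr2a, Htr2c and Bdnf. Genes with provisional names were left out of the first part, and some genes that the rule takes are not reported here. The contrast of SCI on any day with sham, the genes named for it and for the 4 groups, Ccdc71l, the values per library of tissue markers, and the alternatives that leave out libraries by their markers or use a Schwann cell covariate were chosen after the values were seen.

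The other settings tried were DESeq2 1.42.0, limma voom with sample weights, DESeq2 size factors, library size without TMM, no filter, a filter of 1 CPM in every sample of a group, the replicate number as a block, a fit of only the groups compared, and each library left out in turn. Calls shared between days were set beside 40 simulations of unchanged groups, in which the sham libraries were drawn anew too. The test was also tested on simulated data, with 200 changed genes among 18374 in day 3 and sham: edgeR made 113 calls, 5 of them false, DESeq2 225 with 84 false, and voom 107 with 5 false. There edgeR found 14%, 50%, 72% and 80% of changes of 2, 4, 8 and 16-fold, and DESeq2 30%, 70%, 90% and 92%. In comparisons of the simulated days without change edgeR made 1 and 0 calls. Camera gave a p of 5.86e-54 for a changed simulated list and 0.183 for an unchanged one. The simulated genes were drawn independently of each other, so these p-values do not test the preset correlation.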

Results

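RNA sequencing of whole tissue measured gene expression in the lumbar spinal cord (segments L3 to L5) of rats. Samples taken 3, 7 and 14 days after spinal cord injury (SCI) were set against sham samples taken at day 0, with 3 samples in each of the 4 groups. The labels state neither the level and kind of the injury nor whether the samples of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical. No sham group was matched to the later days. Total counts per library, in units of 1e+06, ran from 63 to 79.1. Their group means were 65 ± 0.321 in sham, 76.5 ± 2.47 at day 3, 72.3 ± 2.3 at day 7 and 69.9 ± 6.34 at day 14 (SD, n = 3 each). Of the 23526 genes with counts, 18714 were tested, and these held at least 99.983% of the counts of every library. The common biological coefficient of variation between samples of a group was 0.432. The first principal component took 38.3% of the variance. On it SCI day 3 replicates 1 and 3 lay at 122 and 135, SCI day 3 replicate 2 at -7.04 and the sham libraries between -87.6 and -39.2.

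The libraries differed in tissue composition within groups as well as between them. Slc12a5, the potassium-chloride cotransporter of mature neurons, measured 32.0 and 31.5 CPM (counts scaled to 1e+06 per library) in SCI day 3 replicates 1 and 3, against 383 CPM in replicate 2 of that day and 457 to 609 CPM in sham. Chat, the acetylcholine-synthesising enzyme of motor neurons, followed the same order, with 1.99 and 1.37 CPM in those libraries, 28.8 CPM in replicate 2 and 38.3 to 43.6 CPM in sham. Markers of Schwann cells in nerve roots stood 1.38 log2 units above the sham mean in sham replicate 2 and 2.38 in SCI day 3 replicate 3, and between -1.53 and 1.12 in the other libraries. Scn10a, a sodium channel of sensory ganglion neurons, measured 19.6 CPM in SCI day 3 replicate 2, 79.6 and 131 CPM in SCI day 14 replicates 1 and 2, and at most 1.05 CPM elsewhere. The skeletal muscle actin Acta1 measured 60.1 CPM in SCI day 7 replicate 2 and at most 3.39 CPM elsewhere. Erythrocyte markers stood 3.86 log2 units above the sham mean in SCI day 7 replicate 1. Mitochondrially encoded transcripts took 5.40% and 5.13% of the counts in SCI day 3 replicates 1 and 3, 6.27% in SCI day 14 replicate 2 and 7.80% to 10.5% in the other 9 libraries.

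**Figure D1:**
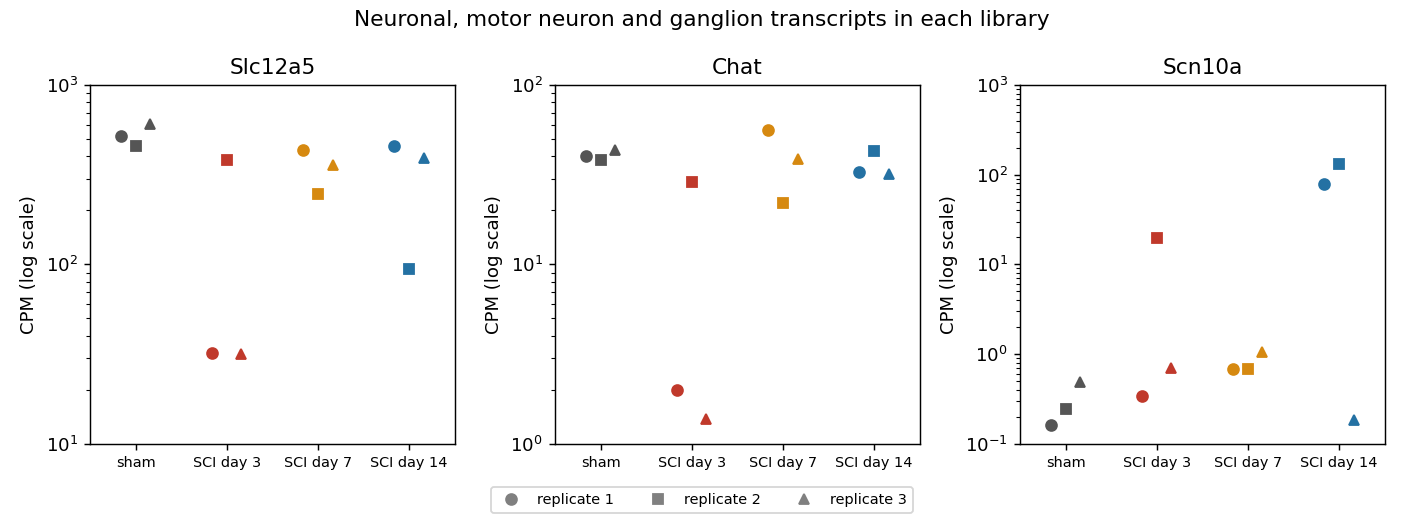
CPM of Slc12a5 (neurons), Chat (motor neurons) and Scn10a (sensory ganglion neurons) on a log axis, 1 point per library and 3 libraries per group. Slc12a5 stood at 32.0 and 31.5 CPM in SCI day 3 replicates 1 and 3, Chat at 1.99 and 1.37 CPM in the same libraries, and Scn10a passed 1.05 CPM in 3 libraries.

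The comparison of SCI day 3 with sham asked how the lumbar cord differed early after the injury. Part of the genes of reactive astrocytes, activated microglia, immediate early transcription and blood vessels rose, and part of those of resting astrocytes and mature oligodendrocytes fell. As whole lists, 0 of 44 passed in camera with an estimated correlation, while fry called 20. In all, 1254 of 18714 genes changed, 1030 of them higher and 224 lower (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At an unadjusted p under 0.05 there were 6597. Most calls lay close to that limit, since 1238 of the 1254 had an adjusted p over 0.03. DESeq2 called 5107 genes, 1248 of them shared with edgeR, and limma voom with sample weights called 6232, with 1246 shared.

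The number of calls at day 3 hung on single libraries, those of other days included. Without SCI day 3 replicate 2 it was 7087, and these held all 1254. Without sham replicate 1, 2 or 3 it was 6, 524 and 1, and without SCI day 3 replicate 1 or 3 it was 8 and 10. Without SCI day 7 replicate 1, 2 or 3 it was 749, 13 and 729, and without SCI day 14 replicate 1, 2 or 3 it was 557, 647 and 18. In a fit of only the SCI day 3 and sham libraries 1 gene passed, and with the replicate number as a block 8 did. Tmem158 alone was called in all 12 of these fits, and 290 genes were called in at least 6 of them. Ccdc71l, Fosb, Aldh1l1 and Cebpb were called in 11, and Mall and Taf10 in 10. Mall, a membrane raft protein, rose by 3.68 on the log2 scale (edgeR adjusted p = 0.0117), and Taf10, a subunit of the general transcription factor TFIID, by 1.56 (edgeR adjusted p = 0.00534).

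**Figure D2:**
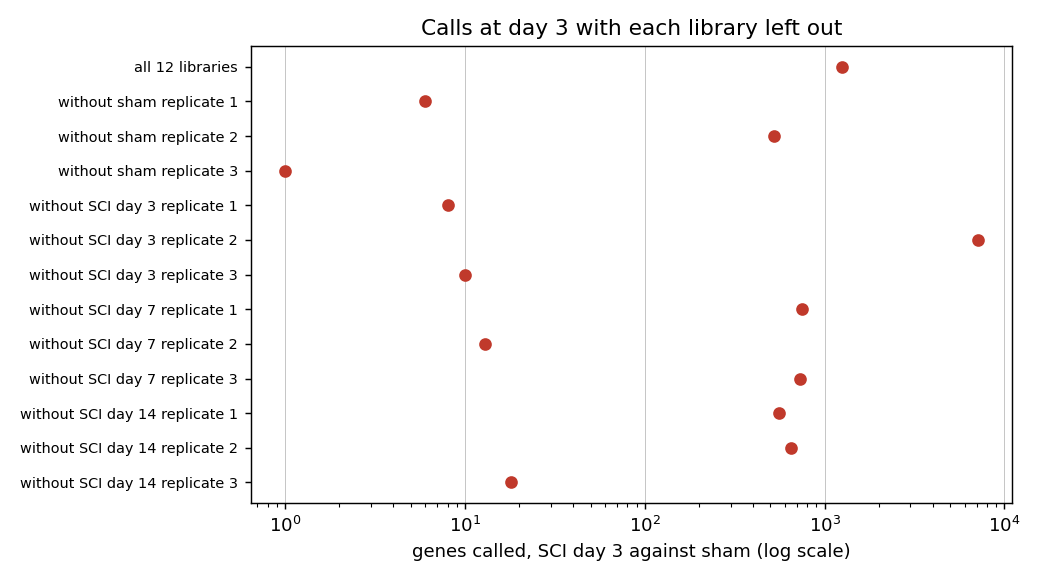
Number of genes called at SCI day 3 against sham (log axis) with each of the 12 libraries left out in turn, beside the 1254 called with all libraries. The number ran from 1 without sham replicate 3 to 7087 without SCI day 3 replicate 2.

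Reactive astrocyte genes gave one of the largest shares of calls at day 3. Of 24 members tested, 16 rose over all genes tested and 22 adjusted over the list alone, with a median log2 fold change of 2.73. Timp1 (ENSRNOG00000010208), an inhibitor of matrix metalloproteinases, rose from 11.3 ± 9.27 CPM in sham to 247 ± 172 CPM (SD, n = 3 each; log2 fold change 4.44 ± 0.762, SE; edgeR adjusted p = 0.0324). Cd44, the hyaluronan receptor, rose from 25.3 ± 2.21 to 177 ± 89.9 CPM, and Socs3, a brake on cytokine signalling, from 3.96 ± 1.28 to 216 ± 133 CPM. The membrane protein Tm4sf1 rose by 2.72 ± 0.428 on the log2 scale (edgeR adjusted p = 0.0324 for each of the 3). Gfap, the astrocyte intermediate filament, had a log2 fold change of 0.69 (edgeR adjusted p = 0.398). Genes of homeostatic astrocytes fell: 4 of 16 over all genes tested and 9 adjusted over the list alone, with a median of -1.34. Aldh1l1 (ENSRNOG00000047023), a folate enzyme, fell from 52.3 ± 7.99 to 14.4 ± 2.50 CPM (log2 fold change -1.86 ± 0.192, SE; edgeR adjusted p = 0.00534). The astrocyte connexins Gjb6 and Gja1 changed by -2.56 and -1.15 (edgeR adjusted p = 0.0391 and 0.0392), and the water channel Aqp4 by -1.64 (edgeR adjusted p = 0.0437). The homeostatic list stood at -1.50 and -2.18 log2 units from the sham mean in SCI day 3 replicates 1 and 3, which had few neuronal transcripts, and at -0.53 in replicate 2. The reactive list stood at 2.86, 3.42 and 2.19 in these libraries. Camera placed the reactive list above and the homeostatic list below the other genes (camera adjusted p = 9.63e-12 and 4.80e-06). For both, adjusted p = 0.421 with an estimated correlation. Without sham replicate 3, the library whose absence cost most calls at day 3, 1 gene in all stayed called, and it is on neither list.

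Genes of activated microglia and phagocytes rose in 9 of 29 members over all genes tested and in 20 adjusted over the list alone, with a median log2 fold change of 2.20. Lgals3, the lectin galectin-3, rose from 9.42 ± 2.96 to 158 ± 108 CPM (SD, n = 3 each; edgeR adjusted p = 0.0324). The scavenger receptor Msr1, the endotoxin co-receptor Cd14 and the lysosomal tetraspanin Cd63 rose by 5.73, 3.92 and 2.20 on the log2 scale (edgeR adjusted p = 0.0338, 0.0358 and 0.0369). Aif1 and Cd68, both general markers of these cells, had log2 fold changes of 1.30 and 2.92 (edgeR adjusted p = 0.112 and 0.0909). Of the 15 homeostatic microglia genes 0 passed, over all genes tested or adjusted over the list alone (median 0.23). Complement genes rose in 2 of 16 (C4b by 2.65 and C6 by 2.47; edgeR adjusted p = 0.0372 and 0.0378) and in 12 adjusted over the list alone (median 1.79). The recognition subunit C1qb had a log2 fold change of 2.60 (edgeR adjusted p = 0.0581). C4b has a near-identical copy, C4a, and how reads that match several genes were counted is not given in the sources used here. Cytokine and chemokine genes rose in 6 of 26 and in 13 adjusted over the list alone. Their median was 2.30, the same with the 3 members at 0 in sham set to their bound. Ccl2, which attracts monocytes, rose from 0.410 ± 0.298 to 33.9 ± 37.3 CPM (edgeR adjusted p = 0.0369). Tgfb1 rose by 2.13 and Cxcl16 by 2.72 on the log2 scale (edgeR adjusted p = 0.0423 and 0.0441). Monocyte and border macrophage markers rose in 1 of 12 (F13a1, a clotting factor chain, by 2.58; edgeR adjusted p = 0.0370) and in 7 adjusted over the list alone (median 1.97). Camera placed the activated microglia, complement, cytokine and monocyte lists above the other genes (camera adjusted p = 5.70e-07, 1.19e-04, 8.15e-06 and 6.79e-04). For each, adjusted p = 0.421 with an estimated correlation. All 4 lists were higher in SCI day 3 replicates 1 and 3, the libraries low in neuronal and mitochondrial transcripts, than in replicate 2. In replicates 1, 2 and 3 they stood at 3.04, 1.19 and 2 (microglia), 1.69, 0.89 and 1.92 (complement), 2.80, 1.42 and 4.12 (cytokines) and 2.43, 1.15 and 2.08 (monocytes) log2 units from the sham mean. None of these calls stayed without sham replicate 3, which left 1 gene called in all.

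Genes of MHC class I antigen presentation rose in 4 of 17 members and in 8 adjusted over the list alone (camera adjusted p = 1.04e-04; adjusted p = 0.421 with an estimated correlation). Among them the immunoproteasome subunit Psmb8 rose by 2.04 and the proteasome activator Psme2 by 1.13 on the log2 scale (edgeR adjusted p = 0.0378 and 0.0436). Interferon response genes rose in 1 of 30, Ifitm3, an antiviral membrane protein, by 2.90 (edgeR adjusted p = 0.0338). In all 5 rose adjusted over the list alone (camera adjusted p = 3.28e-05; adjusted p = 0.527 with an estimated correlation). The MHC class I list stood at 1.08, 0.81 and 1.16 and the interferon list at 1.02, 0.40 and 1.71 in SCI day 3 replicates 1, 2 and 3. MHC class II gave 0 of 8 over all genes tested and 2 adjusted over the list alone. Neutrophil markers gave 0 of 10 and T, B and NK cell markers 0 of 14, over all genes tested and adjusted over the list alone. Camera placed the neutrophil list above the other genes (camera adjusted p = 0.0130; adjusted p = 0.527 with an estimated correlation). The neutrophil list stood 3.58 log2 units above the sham mean in sham replicate 2 and 2.21 to 3.42 above it in the SCI day 3 libraries. In iron and heme handling 2 of 11 members rose, the heme-degrading enzyme Hmox1 by 4.04 and the ferroxidase Cp by 2.36 (edgeR adjusted p = 0.0338 and 0.0358). In all 3 rose adjusted over the list alone (camera adjusted p = 0.0383; adjusted p = 0.527 with an estimated correlation). By library the iron and heme list stood at 1.24, 0.63 and 1.36 in SCI day 3 replicates 1, 2 and 3, lowest in replicate 2. As with the other calls of that day, none of those in these groups stayed called without sham replicate 3, which left 1 gene.

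Immediate early genes, the first to be transcribed after a stimulus, rose in 11 of 17 members and in 12 adjusted over the list alone, with a median log2 fold change of 2.05. Fosb (ENSRNOG00000046667) rose from 1.68 ± 0.793 to 27.4 ± 2.79 CPM (SD, n = 3 each; log2 fold change 4.03 ± 0.422, SE; edgeR adjusted p = 0.00534). Fos rose from 17.8 ± 0.780 to 111 ± 10.4 CPM, and Egr1 and Egr3 rose by 2.05 and 1.68 (edgeR adjusted p = 0.0324 for all 3). Endothelial markers rose in 7 of 13 and in 11 adjusted over the list alone (median 1.12). The junction protein Esam rose by 1.63, the clotting protein Vwf by 1.85 and Egfl7 by 1.95 (edgeR adjusted p = 0.0324, 0.0338 and 0.0354). The endothelial list stood at 1.26, 0.52 and 1.20 log2 units from the sham mean in SCI day 3 replicates 1, 2 and 3, higher in the 2 libraries low in neuronal transcripts. Immediate early genes, at 2.07, 1.34 and 2.36, and fibrosis genes, at 1.73, 0.93 and 2.19, were also higher in those libraries. Pericyte and smooth muscle markers rose in 5 of 11 and in 8 adjusted over the list alone (median 1.33). The muscle filament Des rose from 5.49 ± 1.68 to 31.7 ± 6.85 CPM (edgeR adjusted p = 0.0171) and the receptor Notch3 by 0.78 (edgeR adjusted p = 0.0391). Fibrosis and basement membrane genes rose in 4 of 23 and in 9 adjusted over the list alone (median 1.35). The matrix proteins Thbs2 and Thbs1 rose by 3.82 and 4.10 and the collagen cross-linking enzyme Lox by 2.86 (edgeR adjusted p = 0.0324, 0.0358 and 0.0398). Camera placed these 4 lists above the other genes (camera adjusted p = 4.34e-07, 1.26e-04, 5.03e-03 and 3.67e-06 in that order), each with adjusted p = 0.421 with an estimated correlation. All of these calls, Fosb included, were lost without sham replicate 3, which left 1 gene called.

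Regeneration-associated genes rose in 8 of 22 and in 11 adjusted over the list alone (median 0.997). The transcription factors Klf6 and Cebpd rose by 2.30 and 4.09 and the signal transducer Smad1 by 1.02 (edgeR adjusted p = 0.0332, 0.0354 and 0.0361). Among neurotrophic factors and receptors 2 of 23 rose, Fgf2 by 2.45 and the cytokine Lif by 6.54 (edgeR adjusted p = 0.0324 and 0.0443). In that list 6 rose and 2 fell adjusted over the list alone (median 0.23). Cell cycle genes rose in 3 of 35, the replication helicase subunits Mcm3, Mcm5 and Mcm6 by 2.72, 3.16 and 2.23 (edgeR adjusted p = 0.0414, 0.0485 and 0.0493), and in 30 adjusted over the list alone (median 2.79). The list stood 4.12 log2 units above the sham mean in SCI day 3 replicate 1, and 0.91 and 0.59 above it in replicates 2 and 3. Stress genes of the endoplasmic reticulum and heat shock rose in 3 of 18, among them the chaperone Hspb1 by 2.74 and the kinase-like protein Trib3 by 4.84 (edgeR adjusted p = 0.0338 and 0.0477). There 9 rose adjusted over the list alone (median 0.63). By library the stress list stood at 0.98, 0.42 and 1.14 log2 units from the sham mean in SCI day 3 replicates 1, 2 and 3, higher in the libraries low in neuronal transcripts. Glucocorticoid response genes rose in 3 of 18, among them the metallothioneins Mt2A and Mt1 by 3.88 and 2.98 (edgeR adjusted p = 0.0358 and 0.0439). There 8 rose and 1 fell adjusted over the list alone (median 1.17). By library the glucocorticoid list stood at 1.26, 0.75 and 1.28 in SCI day 3 replicates 1, 2 and 3, again higher in the libraries low in neuronal transcripts. In cholesterol efflux and lipid storage 2 of 14 rose, the oxysterol-forming enzyme Ch25h by 3.53 and the lipid droplet protein Plin2 by 3.08 (edgeR adjusted p = 0.0324 for both). There 4 rose adjusted over the list alone (median 0.23). In the perineuronal net list of 18, Tnc rose by 3.32 and Bcan fell by 2.26 on the log2 scale (edgeR adjusted p = 0.0455 and 0.0477), and 1 went each way adjusted over the list alone. Its median was 0.03, its mean -0.10 and its camera direction down. In the circadian list of 18, Bhlhe40 rose by 0.91 and Per3 fell by 1.14 (edgeR adjusted p = 0.0430 and 0.0395), and 3 rose and 2 fell adjusted over the list alone. Its median was -0.20, its mean 0.01 and its camera direction down. Of these 8 lists, camera placed regeneration, cell cycle, stress and glucocorticoid genes above the other genes (camera adjusted p = 6.38e-03, 3.52e-06, 1.45e-03 and 0.0130), with adjusted p = 0.421, 0.527, 0.421 and 0.527 with an estimated correlation. Without sham replicate 3, 1 gene in all stayed called at day 3, and none of those named here.

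Transcripts of neurons were lower at day 3 in the mean of the group, without calls for most single genes. In the list of GABA and glycine transmission 0 of 29 members passed over all genes tested or over the list alone, although all 29 were lower, with a median log2 fold change of -1.65. The list stood at -2.50, -0.51 and -3.22 log2 units from the sham mean in replicates 1, 2 and 3. The glycine transporter Slc6a9 had a log2 fold change of -1.74 (edgeR adjusted p = 0.0540). Synaptic vesicle genes gave 0 of 22 (median -1.60), neuronal cytoskeleton genes 0 of 14 (median -1.44), ion channel genes 0 of 33 (median -1.32) and motor neuron genes 0 of 14 (median -0.97). These counts were the same adjusted over the list alone. The fusion protein Stx1a, the microtubule protein Mapt and the potassium channel Kcnn1 had log2 fold changes of -0.94, -1.49 and -1.29 (edgeR adjusted p = 0.0705, 0.0554 and 0.0579). Among glutamatergic genes 1 of 29 fell, Grm3, a receptor also made by astrocytes, by 1.92 (edgeR adjusted p = 0.0492). Adjusted over the list alone 0 passed (median -1.49). Among monoamine receptors 1 of 24 rose, and adjusted over the list alone 1 rose and 1 fell (median -1.33). Camera placed the 7 lists below the other genes (camera adjusted p from 5.11e-09 for GABA and glycine to 6.43e-03 for motor neurons). For motor neurons adjusted p = 0.527 with an estimated correlation, and for each of the other 6 adjusted p = 0.421 with an estimated correlation. Chat, Slc12a5, Htr2a, Htr2c and Bdnf had log2 fold changes of -1.92, -1.82, -1.39, -1.93 and -0.22 (edgeR adjusted p = 0.16, 0.171, 0.0953, 0.156 and 0.841). In the result Chat, SCI day 3 against sham, leaving out SCI day 3 replicate 2 gave a log2 fold change of -4.59 with an edgeR adjusted p of 0.000468, while over all alternatives the adjusted p reached 0.919.

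**Figure D3:**
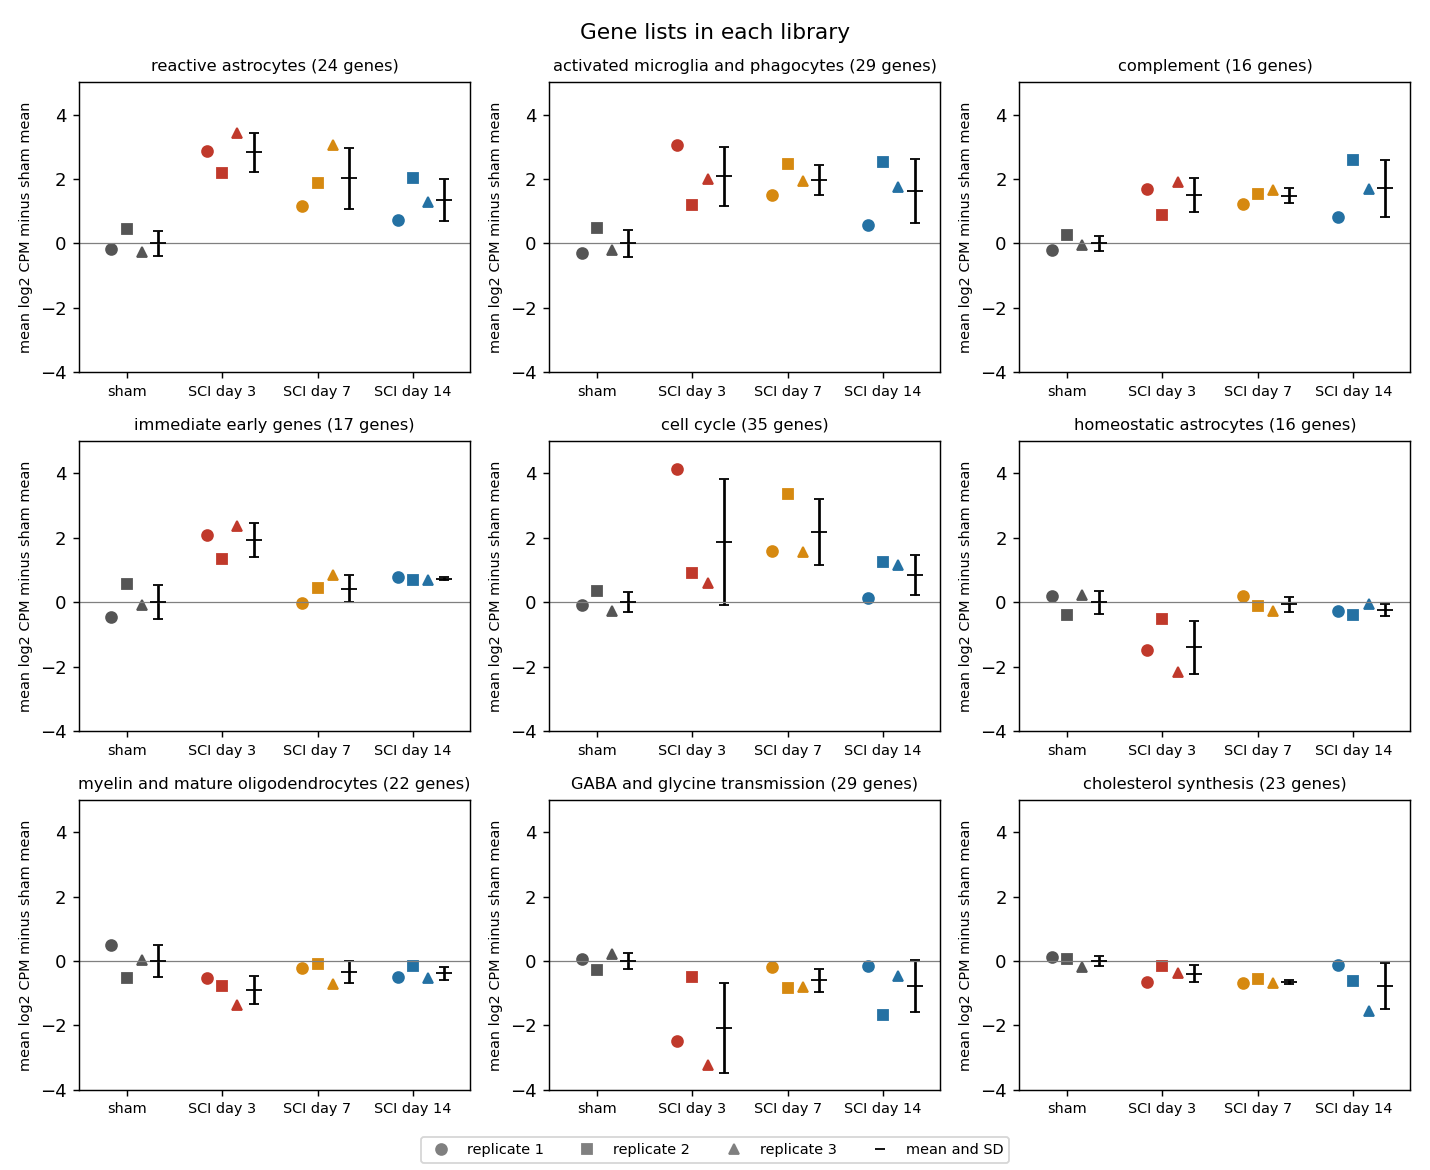
Mean log2 CPM of 9 gene lists relative to the sham mean, 1 point per library with the mean and SD of each group of 3. The list of GABA and glycine transmission lay at -2.50 and -3.22 in SCI day 3 replicates 1 and 3 and at -0.51 in replicate 2, and the reactive astrocyte list lay between 2.19 and 3.42 in these 3 libraries.

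Genes of myelin and mature oligodendrocytes fell in 6 of 22 members at day 3 and in 9 adjusted over the list alone, with a median log2 fold change of -0.71. The list stood at -0.52, -0.79 and -1.37 log2 units from the sham mean in replicates 1, 2 and 3, and at -0.52 in sham replicate 2 as well. It was lowest in the library with the highest Schwann cell markers. Ninj2, Opalin and the acetylaspartate-cleaving enzyme Aspa fell by 1.71, 1.67 and 0.66 on the log2 scale (edgeR adjusted p = 0.0332, 0.0398 and 0.0436). Mbp, a main myelin protein, had a log2 fold change of -0.32 (edgeR adjusted p = 0.493). Among oligodendrocyte progenitor genes 1 of 16 fell, the receptor Gpr17 by 2.41 (edgeR adjusted p = 0.0492), and 0 adjusted over the list alone. Cholesterol synthesis genes gave 0 of 23, with 20 of them lower (median -0.35), oxidative phosphorylation 0 of 32 (median -0.39; -0.44, 0.05 and -0.59 in the 3 libraries) and the mitochondrially encoded transcripts 0 of 13, all 13 lower (median -0.43), over all genes tested and adjusted over the list alone. Camera placed the lists of myelin, cholesterol synthesis, oxidative phosphorylation and mitochondrial transcripts below the other genes (camera adjusted p = 7.91e-05, 0.0124, 8.99e-06 and 4.36e-03), with adjusted p = 0.421, 0.666, 0.527 and 0.577 with an estimated correlation. Markers of the other tissues a lumbar sample can hold gave 0 calls over all genes tested. Schwann cell markers gave 0 of 11 (median 1.06; camera adjusted p = 0.0225, adjusted p = 0.597 with an estimated correlation). For the others these were ganglion neurons 0 of 11 (median 1.81), meninges 0 of 15 (0.33), ependyma 0 of 12 (0.33), erythrocytes 0 of 7 (0.08), skeletal muscle 0 of 9 (0.06) and adipose tissue 0 of 5 (1.51). Adjusted over the list alone, 2 adipose genes rose, 1 meningeal gene rose and 1 fell, and 0 of the others passed. The myelin and progenitor calls, too, were lost without sham replicate 3, which left 1 gene called.

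The genes with the largest changes at day 3, among those at 5 CPM or more in the higher group and with no overlap between the groups, included several secreted signals that sham cord scarcely contained. Il11, a cytokine, had no counts in sham and measured 16.2 ± 17.5 CPM at day 3, at least 1030-fold higher (edgeR adjusted p = 0.0483; the floor is 3 counts over the sham group). On the same floor, Cyp1a1, a target of the aryl hydrocarbon receptor, was at least 352-fold higher, the kinin precursor Kng1 at least 337-fold and the chemokine Ccl3 at least 331-fold (edgeR adjusted p = 0.0263, 0.0492 and 0.0410). Ucn2, a peptide of the corticotropin-releasing family, rose from 0.0478 ± 0.0424 to 9.24 ± 8.72 CPM (SD, n = 3 each; edgeR adjusted p = 0.0430). Replicates 1, 2 and 3 held 13.6, 0.117 and 34.8 CPM of Il11, and 17.5, 0.129 and 10.1 CPM of Ucn2. The largest falls were in Syce1l, the amino acid oxidase Dao, the lipogenic regulator Thrsp, the alanine transaminase Gpt, Btbd17 and the mitochondrial glutamate carrier Slc25a18, with log2 fold changes of -4.99, -3.83, -3.59, -3.58, -3.46 and -2.69 (edgeR adjusted p from 0.0324 to 0.0482). These calls were lost without sham replicate 3, which left 1 gene called.

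The comparison of SCI day 7 with sham followed the response into its later phase. Tmem158 (ENSRNOG00000004757, chromosome 8), a membrane protein first described in Ras-driven senescence, rose from 1.33 ± 0.0259 to 10.6 ± 1.67 CPM (SD, n = 3 each; log2 fold change 3.00 ± 0.220, SE; edgeR adjusted p = 0.00100). Cebpb (ENSRNOG00000057347, chromosome 3), a transcription factor of inflammatory and acute-phase genes, rose from 0.532 ± 0.167 to 25.2 ± 12.3 CPM (log2 fold change 5.56 ± 0.627, SE; edgeR adjusted p = 0.0212). Ccdc71l (ENSRNOG00000039207, chromosome 6) rose by 2.97 on the log2 scale (edgeR adjusted p = 0.0212). It lay under 5 CPM and was named only after its values were seen. These 3 genes were all that passed, 0 genes fell, and 1850 had an unadjusted p under 0.05. DESeq2 called 507 genes and voom 276. The 3 calls became 1 without sham replicate 1, 2 or 3, SCI day 7 replicate 3 or SCI day 14 replicate 3. They became 5 and 7 without SCI day 3 replicate 1 and 2, and 89 in a fit of only the SCI day 7 and sham libraries.

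No gene list had a member that passed over all genes tested at day 7, yet several glial and immune lists lay higher. Reactive astrocyte genes had a median log2 fold change of 2.04, with 19 of 24 passing adjusted over the list alone. Gfap (ENSRNOG00000002919) measured 7652 ± 673 CPM against 1893 ± 770 CPM in sham (log2 fold change 2.02, edgeR adjusted p = 0.309). The urea transporter Slc14a1 and Hspb1 had log2 fold changes of 1.39 and 2.94 (edgeR adjusted p = 0.124 and 0.168). Activated microglia genes had a median of 2.04, with 17 of 29 passing adjusted over the list alone. Lgals3, the antibody receptor Fcgr3a, Aif1 and Cd68 had log2 fold changes of 3.72, 3.95, 2.34 and 3.11 (edgeR adjusted p = 0.171, 0.251, 0.244 and 0.386). Adjusted over the list alone, complement genes passed in 9 of 16 (median 1.39), monocyte markers in 6 of 12 (median 1.74), cytokines in 6 of 26 (median 1.70) and MHC class I genes in 4 of 17 (median 0.79). In the same way homeostatic microglia passed in 3 of 15 (median 0.87), interferon response genes in 3 of 30 (median 0.69), pericyte markers in 3 of 11 (median 0.49) and fibrosis genes in 4 of 23 (median 0.28). Some of these lists overlapped sham. SCI day 7 replicate 1 lay below sham replicate 2 for cytokines (0.49 against 0.77 log2 units from the sham mean) and MHC class I (0.26 against 0.49). The same held for monocyte markers (0.61 against 0.74) and fibrosis genes (-0.12 against 0.79). In the other lists named so far every SCI day 7 library lay above every sham library, for interferon genes only just (0.28 against 0.27). C1qb, C4a, Ccl2, Des and Thbs2 had log2 fold changes of 3.19, 1.41, 5.03, 1.94 and 3.51 (edgeR adjusted p = 0.251, 0.251, 0.252, 0.124 and 0.186). All 35 cell cycle genes were higher, with a median of 2.40 and 0 passing adjusted over the list alone (Cdk1 3.85 and Tk1 3.36, edgeR adjusted p = 0.343 and 0.346). All 23 cholesterol synthesis genes were lower, with a median of -0.66 and 0 passing adjusted over the list alone (Tm7sf2 -0.97 and Lss -0.87, edgeR adjusted p = 0.379 and 0.386). The cholesterol list stood at -0.70, -0.57 and -0.68 in the 3 libraries. Myelin and mature oligodendrocyte genes had a median of -0.47, with 16 of 22 lower (camera adjusted p = 2.45e-03, or 0.551 with an estimated correlation). By library the myelin list stood at -0.21, -0.09 and -0.72, against -0.52 to 0.5 in sham. Homeostatic astrocyte genes (median -0.16) and progenitor genes (-0.03) were not called by camera. Hmox1 had a log2 fold change of 3.91 (edgeR adjusted p = 0.217). Camera placed 21 of the 44 lists above and 6 below the other genes, led by reactive astrocytes (camera adjusted p = 2.00e-17), cell cycle (2.02e-15) and activated microglia (7.33e-14). Each of these had adjusted p = 0.508 with an estimated correlation. With an estimated correlation, and in fry, 0 lists passed.

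Neuronal genes lay closer to sham at day 7 than at day 3 in their medians, with -0.58 for GABA and glycine transmission and -0.55 for synaptic vesicle genes (camera adjusted p = 6.78e-04 and 4.43e-04; adjusted p = 0.594 and 0.580 with an estimated correlation). In both, 0 passed adjusted over the list alone. By library the GABA and glycine list stood at -0.18, -0.84 and -0.80 log2 units from the sham mean at day 7, against -2.50, -0.51 and -3.22 at day 3. SCI day 3 replicate 2 thus lay closer to sham than SCI day 7 replicates 2 and 3, and the difference between these days rested on SCI day 3 replicates 1 and 3. Chat, Slc12a5, Htr2a, Htr2c and Bdnf had log2 fold changes of -0.06, -0.61, 0.06, -0.81 and -0.32 (edgeR adjusted p = 0.985, 0.855, 0.976, 0.808 and 0.902), and Mbp of -0.48 (edgeR adjusted p = 0.681). Erythrocyte markers had a median of 2.83, with 4 of 7 passing adjusted over the list alone (camera adjusted p = 3.67e-04; adjusted p = 0.508 with an estimated correlation). They stood highest in SCI day 7 replicate 1, at 3.86 log2 units above the sham mean. Skeletal muscle markers had a median of 2.91 (camera adjusted p = 0.0410; adjusted p = 0.580 with an estimated correlation), and stood at 4.54 in SCI day 7 replicate 2. Median, mean and camera direction differed in sign for neutrophil markers (median -0.99, camera up), T, B and NK cell markers (-0.49, up), meninges (0.25, down), perineuronal nets (-0.14, up) and oxidative phosphorylation (median -0.10, mean 0.01, down), none of which camera called.

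The comparison of SCI day 14 with sham covered the latest day sampled. Tmem158 rose to 13.6 ± 3.30 CPM against 1.33 ± 0.0259 CPM in sham (SD, n = 3 each; log2 fold change 3.36 ± 0.224, SE; edgeR adjusted p = 0.000375), and Cebpb to 18.1 ± 8.25 against 0.532 ± 0.167 CPM (5.08 ± 0.614; edgeR adjusted p = 0.0408). Ccdc71l, named after its values were seen, rose by 2.92 on the log2 scale (edgeR adjusted p = 0.0299). These 3 genes were again all that passed, 0 genes fell, and 1384 had an unadjusted p under 0.05. DESeq2 called 204 genes and voom 9. The number of calls was 1 without sham replicate 1, 2 or 3, SCI day 3 replicate 1 or 3, or SCI day 14 replicate 2, and 0 in a fit of only the SCI day 14 and sham libraries.

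Complement genes stood out among the lists at day 14, with 14 of 16 passing adjusted over the list alone and a median log2 fold change of 1.87. C4a and C4b, near-identical copies, had log2 fold changes of 1.84 and 2.48 (edgeR adjusted p = 0.406 and 0.502). Activated microglia genes passed in 11 of 29 adjusted over the list alone (median 1.62). Lgals3, the phagocyte glycoprotein Gpnmb, Aif1 and Cd68 had log2 fold changes of 2.78, 4.27, 1.58 and 3.94 (edgeR adjusted p = 0.502, 0.553, 0.594 and 0.553). Both lists were highest in replicate 2, the library of that day lowest in Slc12a5, with complement at 0.81, 2.60 and 1.70 and microglia at 0.56, 2.54 and 1.75 log2 units from the sham mean in replicates 1, 2 and 3. Reactive astrocyte genes passed in 6 of 24 adjusted over the list alone (median 1.41), and Cp, the oncostatin receptor Osmr and Gfap stood at 1.71, 2.19 and 0.68 (edgeR adjusted p = 0.553, 0.592 and 0.886). Fibrosis genes passed in 6 of 23 adjusted over the list alone (median 0.82), with Lox at 2.96 and the matrix proteoglycan Bgn at 1.37 (edgeR adjusted p = 0.502 and 0.511). Markers of meninges and fibroblasts passed in 2 of 15 adjusted over the list alone (median 0.79; camera adjusted p = 3.90e-03; adjusted p = 0.480 with an estimated correlation), and stood at 0.94, 1.68 and -0.13 in the 3 libraries. Cholesterol synthesis genes were lower in 23 of 23, with 0 adjusted over the list alone (median -0.72; Sc5d -0.83 and Tm7sf2 -1.01, edgeR adjusted p = 0.594 for both). The list stood at -0.13, -0.63 and -1.54 in the 3 libraries. Cholesterol efflux and lipid storage had 2 of 14 passing adjusted over the list alone (median 0.72; Ch25h 2.21 and the cholesterol exporter Abca1 1.85, edgeR adjusted p = 0.502 and 0.547). The reactive astrocyte (0.72, 2.04 and 1.27), fibrosis (1.12, 1.64 and 1.27) and cholesterol efflux lists (0.26, 1.17 and 0.80) were also highest in replicate 2. Over all genes tested, 0 members of any list passed. Camera placed 21 lists above and 8 below the other genes. For cholesterol synthesis, complement, microglia, fibrosis, astrocytes and cholesterol efflux the camera adjusted p was 4.65e-15, 3.63e-12, 3.63e-12, 4.26e-11, 7.38e-11 and 1.67e-05. Each of these had adjusted p = 0.346 with an estimated correlation. With an estimated correlation, and in fry, 0 lists passed. The neurotrophin receptor Ngfr and Des had log2 fold changes of 3.53 and 1.26 (edgeR adjusted p = 0.349 and 0.502).

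Ganglion markers were high in part of the day 14 group. Scn11a, Avil and Scn10a, 3 genes of sensory ganglion neurons, had log2 fold changes of 8.37, 4.62 and 7.88 (edgeR adjusted p = 0.547, 0.547 and 0.553). Adjusted over the list alone 8 of 11 markers passed, with a median of 4.37, the same with the 1 member at 0 in sham set to its bound. The list stood at 4.57 and 5.28 log2 units above the sham mean in SCI day 14 replicates 1 and 2 and at 0.03 in replicate 3 (camera adjusted p = 3.37e-06; adjusted p = 0.403 with an estimated correlation). In the result Scn10a, SCI day 14 against sham, the log2 fold change was -0.68 with the 3 libraries high in these markers left out. Genes of the cord's own neurons had medians of -0.69 for GABA and glycine transmission and -0.49 for synaptic vesicles (camera adjusted p = 1.06e-05 and 5.05e-04; adjusted p = 0.488 and 0.629 with an estimated correlation). Replicate 2 lay lowest, with the lists at -0.17, -1.68 and -0.47, and at -0.06, -1.07 and -0.44, log2 units from the sham mean in replicates 1, 2 and 3. Slc12a5 measured 456, 94.7 and 391 CPM in these libraries. Chat, Slc12a5, Htr2a, Htr2c and Bdnf had log2 fold changes of -0.18, -0.75, -0.27, -0.75 and -0.12 (edgeR adjusted p = 0.969, 0.899, 0.921, 0.899 and 0.976), and Mbp of -0.58 (edgeR adjusted p = 0.780). Myelin and mature oligodendrocyte genes had a median of -0.42, with 20 of 22 lower (camera adjusted p = 2.49e-04, or 0.454 with an estimated correlation). By library the list stood at -0.49, -0.15 and -0.52 log2 units from the sham mean, within the range of -0.52 to 0.5 of the sham libraries. Neutrophil markers (median -0.58, camera up) and T, B and NK cell markers (0.38, down) differed in sign between median and test, and camera called neither.

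The contrast of SCI on any day with sham, the mean of the 3 SCI groups, was chosen after the data were seen. It gave 9 genes, all higher, with 3578 at an unadjusted p under 0.05: Tmem158, Ccdc71l, Cebpb, Taf10, Hnrnpa0, Jund, H1f10, Apold1 and 1 gene without a symbol. Tmem158 was higher by 3.10 ± 0.204 on the log2 scale and Cebpb by 5.75 ± 0.606 (SE; edgeR adjusted p = 0.000335 and 0.0109). Taf10, the RNA-binding protein Hnrnpa0, the AP-1 subunit Jund, the linker histone H1f10 and the endothelial early-response gene Apold1 were higher by 1.30, 1.12, 0.81, 2.35 and 2.03 (edgeR adjusted p = 0.0109, 0.0408, 0.0472, 0.0472 and 0.0474). Every SCI library lay above every sham library for Tmem158 (8.72 to 17.2 against 1.30 to 1.34 CPM), Ccdc71l (2.42 to 5.85 against 0.470 to 0.507 CPM) and Cebpb (10 to 74.5 against 0.356 to 0.687 CPM). Over all genes 723 were so placed, and 414 had every SCI library below every sham library, against 85.1 by chance each way (0.455% of genes). That figure is an expectation without a spread, and genes are not independent of each other, so these counts do not exclude chance. DESeq2 called 1489 genes and voom 4008. The count of 9 became 1 without sham replicate 1, 2 or 3, and 5, 3341 and 5 without SCI day 3 replicate 1, 2 or 3. It became 5, 4 and 4 without SCI day 7 replicate 1, 2 or 3, and 16, 4 and 4 without SCI day 14 replicate 1, 2 or 3. Tmem158 was called in all 12 fits.

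**Figure D4:**
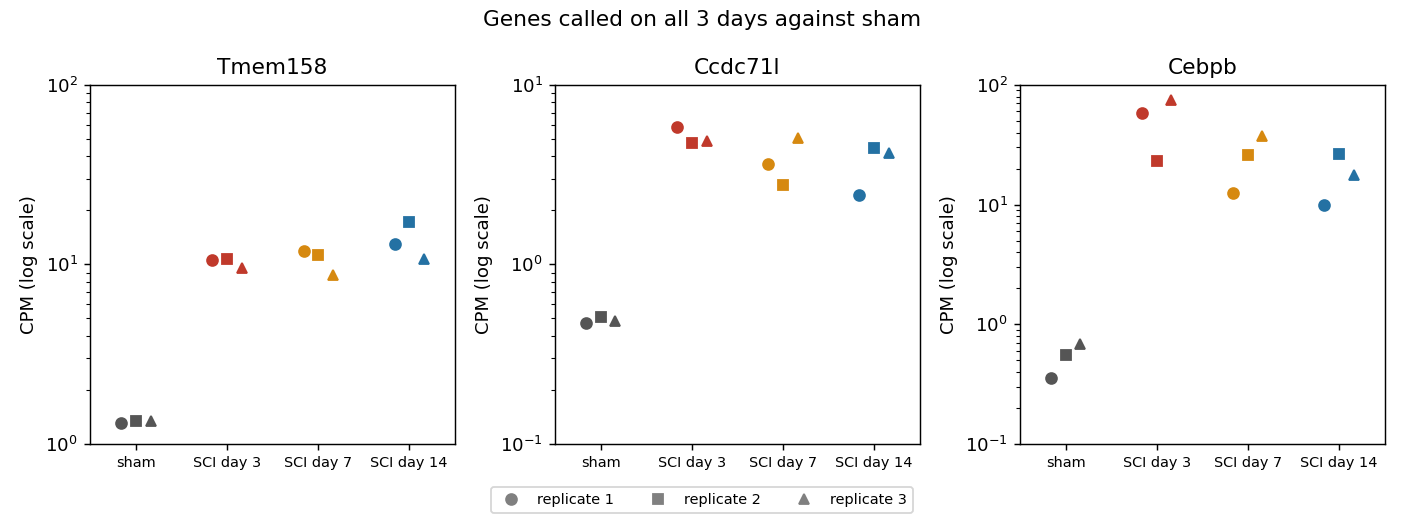
CPM of Tmem158, Ccdc71l and Cebpb on a log axis, 1 point per library and 3 libraries per group. All 9 SCI libraries lay above all 3 sham libraries, at 8.72 to 17.2 against 1.30 to 1.34 CPM for Tmem158, 2.42 to 5.85 against 0.470 to 0.507 CPM for Ccdc71l and 10 to 74.5 against 0.356 to 0.687 CPM for Cebpb.

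Over the 4 groups together 8 genes differed, with 3643 at an unadjusted p under 0.05: Tmem158, Fosb, Mall, Dusp5, Taf10, Ccdc71l, Aldh1l1 and Cebpb (edgeR adjusted p from 0.00324 for Tmem158 to 0.0350 for Cebpb). They were named after their values were seen. Dusp5, a phosphatase that acts on ERK kinase, had a log2 fold change of 2.92 at day 3 (edgeR adjusted p = 0.0177). DESeq2 called 2631 genes and voom 3116. The count of 8 became 2, 2 and 0 without sham replicate 1, 2 or 3, and 1, 4330 and 1 without SCI day 3 replicate 1, 2 or 3. It became 1 without SCI day 7 replicate 1 or 2, and 4 without SCI day 14 replicate 3.

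The 3 comparisons between SCI days asked how the injured cord differed over time. The homeostatic astrocyte list was higher at day 7 than at day 3 in 16 of 16 members (median log2 fold change 1.22, 10 passing adjusted over the list alone). The immediate early list was lower in 17 of 17 (median -1.46, 6 adjusted over the list alone). GABA and glycine, vesicle, cytoskeleton and channel genes had medians of 0.96, 0.99, 1.17 and 0.94 in that comparison, in which SCI day 3 replicates 1 and 3 held few neuronal transcripts. Endothelial markers had a median of -0.93 (6 adjusted over the list alone) and mitochondrially encoded transcripts of 0.52. For each list named for these days adjusted p = 0.686 with an estimated correlation. From day 7 to day 14 the cell cycle list was lower in 35 of 35 (median -1.64, 0 adjusted over the list alone). The reactive astrocyte list had a median of -0.70, erythrocyte markers of -2.34 and ganglion markers of 4.15 (8 adjusted over the list alone), the last high in SCI day 14 replicates 1 and 2. For each of these 4 lists adjusted p = 0.830 with an estimated correlation. From day 3 to day 14 the reactive astrocyte list was lower in 24 of 24 (median -1.44, 7 adjusted over the list alone), the immediate early list had a median of -1.31 (6), endothelial markers of -0.96 (10) and homeostatic astrocytes of 1.04 (7). Each of these had adjusted p = 0.629 with an estimated correlation. No single gene passed edgeR's quasi-likelihood test in any of the 3: 0 genes from day 3 to day 7 (2773 at an unadjusted p under 0.05), 0 from day 7 to day 14 (686) and 0 from day 3 to day 14 (3343). DESeq2 called 230, 50 and 1096 genes and voom 2168, 0 and 3291. Median, mean and camera direction differed in sign for cell cycle, perineuronal net and adipose genes from day 3 to day 7, and for neurotrophic, perineuronal net, erythrocyte, skeletal muscle and adipose genes from day 3 to day 14. From day 7 to day 14 they did so for homeostatic microglia, MHC class II, cytoskeleton, glutamatergic, regeneration, circadian, iron, pericyte, neutrophil and lymphocyte genes, and camera called none of these. Without SCI day 3 replicate 2 the first and last gene counts were 3605 and 4342, and without SCI day 14 replicate 1 they were 2 and 1.

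All calls at days 7 and 14 against sham were also called at day 3, where most of the 1254 called genes were not shared. Tmem158, Ccdc71l and Cebpb were called higher on every day, so each pair of days shared 3 genes, against 0.165, 0.165 and 0.000481 expected of independent lists. The shared count was 0 in 40 simulations in which all 12 libraries, sham included, were drawn from the sham means. Groups simulated without change give few calls of any kind, so that 0 does not bear on these 3 genes. Across genes, which are not independent replicates, the log2 fold changes correlated between days with r = 0.703, 0.659 and 0.669 for days 3 and 7, 3 and 14, and 7 and 14, where the shared sham alone gave 0.504, 0.506 and 0.505. The shared sham group of 3 cannot be parted into a pair of sets of at least 2, so part of the excess may come from the shared controls. The shared count ran from 1 without any of the sham libraries or SCI day 14 replicate 3 to 7 without SCI day 3 replicate 2.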

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

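All tests of explanations in this part were chosen after the results they bear on had been seen. The plan fixed the lists and named list tests for each day against sham, not between days. Gene lists that differed between SCI days came up because a test of the difference itself, camera with the preset correlation, called 19 of 44 lists from day 3 to day 7, 14 from day 7 to day 14 and 25 from day 3 to day 14. With an estimated correlation 0 lists passed in each.

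Neuronal transcripts were low in SCI day 3 replicates 1 and 3 and close to sham in replicate 2. Dilution of the cord by nerve root tissue would lower all cord cell types alike. The median of oligodendrocyte progenitor genes stood above that of neuronal genes by 2.32 log2 units in replicate 1 and 1.14 in replicate 3. Resampling genes within each library gave intervals of 1.52 to 3.06 and 0.70 to 3.77. Genes of 1 library are not independent replicates, so these intervals do not measure the spread between samples. The gaps argue against dilution as the whole cause if the injury left progenitor transcripts unchanged, which was not tested. The progenitor median itself stood at 0.21 in replicate 1 and at -2.12 in replicate 3, the library with the highest Schwann cell markers, so dilution may have contributed there. A sham library under the label of SCI day 3 replicate 2 is argued against by its reactive astrocyte list, 2.19 log2 units above the sham mean, where the highest sham library stood at 0.45. Only a swap with sham was tested. The log2 CPM of SCI day 3 replicate 2 correlated at r = 0.966 with sham replicate 2 and SCI day 14 replicate 1, and at 0.916 and 0.922 with SCI day 3 replicates 1 and 3. Another level of the cord cannot be told apart. Hoxb13, a marker of caudal segments, had a Pearson r of -0.203 with the neuronal lists over 12 libraries (permutation p = 0.549). Spearman rho was -0.232 (permutation p = 0.466). The r was -0.547, without a test, when sham replicate 2 and SCI day 3 replicate 2 were left out. Those libraries had the most Hoxb13 (19.3 and 10.1 CPM) and no such loss of neuronal transcripts (Slc12a5 at 457 and 383 CPM), so leaving them out favours this explanation. SCI day 3 replicates 1 and 3, low in neuronal transcripts, held 0.0731 and 4.37 CPM of Hoxb13. No sample's level is recorded apart from L3 to L5. A loss of neurons or of their transcripts after the injury in some samples, and uneven dissection, may both give this pattern and were not tested.

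Markers of dorsal root ganglion neurons were high in SCI day 3 replicate 2 and SCI day 14 replicates 1 and 2. Ganglion tissue in these libraries would raise all such markers together, and 10 of 11 lay above the other 9 libraries in all 3; Prph, which cord motor neurons also express, did not, with 276 CPM in the lowest of them against 295 CPM in the highest of the others. Ganglion tissue carried along in dissection is therefore a candidate source, found and tested on the same libraries. Avil reached 37.7, 88.5 and 151 CPM in these libraries and at most 6.91 CPM in the others, and expression of these genes by cord cells after injury was not tested.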

How the results depend on the processing

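The alternatives that leave out libraries by their markers, the Schwann cell covariate and all results for SCI on any day were chosen after the data were seen; the others were planned. Counts are given in the order day 3, day 7 and day 14 against sham, day 7 against 3, day 14 against 7, day 14 against 3, SCI on any day, the 4 groups, and genes shared between days, with all libraries giving 1254, 3, 3, 0, 0, 0, 9, 8 and 3. With DESeq2 size factors, library size only, or a filter of 1 CPM in every sample of a group, the 9 counts stayed within 1.5 times these values (1066, 1394 and 1658 at day 3), and scaling moved the median of all genes by -0.022 to 0.043 on the log2 scale.

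DESeq2 gave 5107, 507, 204, 230, 50, 1096, 1489, 2631 and 471, and in the simulated data it made more false calls. Limma voom with sample weights gave 6232, 276, 9, 2168, 0, 3291, 4008, 3116 and 221; its weights ran from 0.265 for SCI day 3 replicate 2 to 3.39 for sham replicate 3. Without a filter the day 3 count was 733, with more genes tested. Only the 2 groups compared gave 1, 89, 0, 0, 0, 0 and, for shared genes, 0, and can give no value for SCI on any day or the 4 groups. The replicate block gave 8, 1, 1, 1, 0, 0, 5, 3 and 1; the replicate numbers did not pair the libraries, since libraries of 1 number correlated with r from -0.343 to 0.247 after group means were removed (median -0.04).

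The 2 nerve root libraries left out (sham replicate 2 and SCI day 3 replicate 3) gave 3, 0, 1, 0, 0, 0, 3, 0 and 1. The 2 low-neuron day 3 libraries left out (replicates 1 and 3) gave 1, 2, 1, 0, 0, 0, 6, 1 and 1, with the lone SCI day 3 library assumed to vary like the other groups. The 3 ganglion libraries left out (SCI day 3 replicate 2, SCI day 14 replicates 1 and 2) gave 6787, 8, 3, 3222, 0, 2088, 2409, 3785 and 7, with a lone SCI day 14 library. The Schwann marker covariate gave 9, 3, 1, 0, 0, 1, 5, 2 and 3. Leaving out each library in turn gave 1 (sham replicate 3) to 7087 (SCI day 3 replicate 2) at day 3, 1 to 7 at day 7, 1 to 3 at day 14, 0 to 3605 for day 7 against 3, 0 for day 14 against 7, 0 to 4342 for day 14 against 3, 1 to 3341 for SCI on any day, 0 to 4330 for the 4 groups and 1 to 7 for shared genes. Except where fewer libraries or more genes tested account for a count, the cause was not tested.

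Camera called 30, 27 and 29 lists at days 3, 7 and 14, and 28 to 31, 21 to 27 and 21 to 30 with each library left out. With an estimated correlation it called 0, 0 and 0, and fry called 20, 0 and 0. The other alternatives gave 22 to 31, 24 to 27 and 24 to 30.

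Among the results of named genes, DESeq2 kept 113 on the same side of the limit and raised 38 past it, and the replicate block took 78 below it. Fold changes near 0 changed sign. Chat at day 7 gave 0.02 with the replicate block, and -0.42 to 0.22 with a library left out. Htr2a at day 7 gave -0.02 with the replicate block, -0.07 with voom, -0.11 without the nerve root libraries, -0.02 with the Schwann covariate, and -0.47 to 0.30 with a library left out. Bdnf at day 3 gave 0.08 without the nerve root libraries, 0.55 without the low-neuron libraries, 0.20 with the Schwann covariate, and -0.84 to 0.28 with a library left out. Bdnf at day 14 gave 0.26 with the Schwann covariate and -0.54 to 0.18 with a library left out. Scn10a at day 14 gave -0.68 without the ganglion libraries, which held most of its counts. The alternative of another pseudocount was not run, since counts were deposited. At 63 to 79.1 (1e+06 counts) per library, depth leaves only a lower bound on the fold of genes at 0 in sham.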

Other observations

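All tests of explanations in this part were chosen after the results they bear on had been seen; the counts over other splits of the samples were planned for the comparisons fixed in advance, and not for SCI on any day.

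Averaged over the 3 SCI days, a contrast chosen after the data were seen, camera placed 20 lists above and 10 below the other genes. The highest were reactive astrocytes (camera adjusted p = 4.67e-15), activated microglia (2.38e-11) and cell cycle genes (1.32e-08), and the lowest synaptic vesicle genes (1.43e-07), cholesterol synthesis and GABA and glycine transmission (3.93e-08 for both). Each had adjusted p = 0.414 with an estimated correlation, under which 0 lists passed, and fry called 8. Neutrophil markers had a median of -0.26 and a camera direction of up (camera adjusted p = 0.0264; adjusted p = 0.507 with an estimated correlation).

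Positional and lineage genes differed between libraries of 1 group. Hoxb13, a gene of caudal segments, measured 19.3 CPM in sham replicate 2, 10.1 and 4.37 CPM in SCI day 3 replicates 2 and 3, and at most 1.12 CPM elsewhere. Hoxc10, a lumbar positional gene, measured 13.6 and 12.7 CPM in SCI day 3 replicates 1 and 3, 20.6 CPM in SCI day 14 replicate 2 and 36.7 to 56.6 CPM in the other libraries. The libraries low in Hoxc10 were also those lowest in Slc12a5 (32, 31.5 and 94.7 CPM), so its level cannot be read as position alone. In sham replicates 1, 2 and 3, Hoxc11 measured 0.275, 20.6 and 26 CPM and Hoxc8 17.6, 2.61 and 10.1 CPM. Olig2, a factor of the oligodendrocyte lineage, measured 13.8 CPM in SCI day 3 replicate 3 against 73.5 and 65.4 CPM in replicates 1 and 2.

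Tmem158, Ccdc71l and Cebpb were higher in all 9 SCI libraries than in any sham library. Library depth is argued against, since SCI day 14 replicate 3, with fewer counts than any sham library, held at least 7.95 times the CPM of the highest sham library for each of the 3. Genes with a single exon (a gene model of at least 0.97 of its span) made up 7 of the 9 called for SCI on any day (77.8% against 8.63% of the others; Fisher exact p = 1.11e-06), so a library preparation that recovered some single-exon genes differently in sham may have contributed, although such genes as a class did not shift (median log2 fold change 0.007 over 1621 genes) and were 8.02% of the 723 genes with all SCI libraries above all sham libraries against 8.69% of the others (Fisher exact p = 0.589). At day 3 against sham they were 75 of the 1254 called genes (5.98%), a smaller share than among the other genes (Fisher exact p = 3.25e-04). At days 7 and 14 against sham all 3 called genes, Tmem158, Ccdc71l and Cebpb, were single-exon (Fisher exact p = 6.49e-04 on each day). No preparation dates are given, so a batch that follows the groups and a lasting response to injury cannot be told apart for these genes, and the latter was not tested.

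Each comparison of 3 libraries with 3 others has 10 splits, too few for a share under 0.05 (the smallest share is 0.1). At day 3 the real split gave 1254 genes and the highest other 0, at day 7 it gave 3 and 1, and at day 14 it gave 3 and 0, so that 1 split was as large in each. Between days the real splits gave 0 genes, so all 10 splits of each pair gave at least as many. From day 3 to day 14 a split that set SCI day 3 replicate 2 with SCI day 14 replicates 1 and 3 against the rest gave 1775, which points to a structure of the samples other than the day. The rest were SCI day 3 replicates 1 and 3 and SCI day 14 replicate 2, the libraries lowest in Slc12a5 (32, 31.5 and 94.7 CPM). They were also lowest in mitochondrially encoded transcripts (5.40%, 5.13% and 6.27% of the counts). For SCI on any day, a contrast chosen after the data were seen, 4 of 100 regroupings, the real one included, gave at least the real 9 genes, and the highest other gave 5115. Because the contrast was not planned, that share was not used to judge chance. For the 4 groups 9 of 100 gave at least the real 8, so chance was not excluded, and the highest other gave 1453; both again point to a structure of the samples.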
